A study of Homo sapiens with 6 samples.

How the data were processed

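RNA bound to tagged polysomes was isolated from RUES2-derived Purkinje cells with GFP antibodies after cycloheximide treatment, and 1 ng of RNA was amplified to full-length cDNA and sequenced as single reads, per the labels' protocols. Salmon 0.8.2, DESeq2 1.20.0, bcl2fastq and the genome build hg19 are named in the submitters' processing notes, with no role or order. Each of the 6 libraries has a deposited table of 69548 transcripts with UCSC known gene identifiers. Per the file headers, the authors deposited estimated counts (expected counts, the number of reads that the quantifier assigned to each transcript) and TPM (a relative transcript abundance, the estimated counts divided by effective length and rescaled within the library). Whether mouse reads were removed before counting, and whether strand was used, is not given in the sources used here. Transcript names, lengths and effective lengths were identical in the 6 tables.

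The files do not pair transcripts with genes, and the reference tables given here do not list these identifiers. A sample of the UCSC hg19 known gene table that is distributed with the Bioconductor package GenomicFeatures 1.54.1 (178 transcripts) was used to pair identifiers with Entrez genes and to give hg19 exon positions. Gene symbols for those Entrez numbers came from the RefSeq gene table given for assembly GRCh38.p14, of which no coordinates were used. Of the 178 transcripts, 147 were in the files, 1 had no symbol, and 146 transcripts of 43 genes (0.21% of transcripts) were named. The lengths of all 146 equalled those in the files. This source of names was chosen after the files were seen, without regard to values, and every gene it names is in the tables.

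Groups and replicate numbers came from the sample titles. The rule for named genes, fixed before the data were examined, took 6 named genes, the 5 largest changes each way among transcripts past the threshold with a mean of at least 20 CPM and no overlap between groups, and members of 33 gene lists. Without gene names for most transcripts, the 6 genes and the lists were not tested, and of the largest changes only 2 each way are printed. The 43 genes above were reported in their place. The transcripts singled out within genes were chosen after their values were seen.

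Estimated counts were rounded to whole numbers and tested per transcript, as foreseen where transcripts cannot be joined to genes. The main test was the quasi-likelihood F-test of edgeR 4.0.16 with the group as the only term, default filtering (minimum count 10, minimum total 15), TMM normalization, dispersion estimated over all 6 libraries and Benjamini-Hochberg adjustment, two-sided, in R 4.3.3. For named genes the same test was run after the transcripts of each gene were summed and the other transcripts kept. Standard errors are the absolute log2 fold change divided by the square root of the F statistic. Where a group had 0 reads, a fold is a bound against 3 counts over that group, so that leaving out a library of that group lowers the bound to 0.602 to 0.735 times by construction. Such bounds cover counting error only, since reads without molecular identifiers are not independent molecules. For single transcripts they also take the quantifier's assignment of reads between transcripts as given, and do not cover its error. Over a group, 3 counts are 0.0945 CPM at Day 24 and 0.0962 CPM at Day +95. Tested transcripts held 98.8% of all reads. Shares of a gene's reads per transcript were computed for genes with at least 50 reads in every library. Group comparisons of single values used exact permutation over the 10 splits of the libraries, whose smallest two-sided p is 0.1.

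Alternatives were DESeq2 1.42.0 (Wald test), edgeR with DESeq2's size factors, library totals without TMM, no low-count filter, a mean of at least 10 CPM, limma 3.58.1 on log2(TPM + 1) (a scale that understates changes of low values), the replicate number as a block, removal of the 20 most abundant transcripts, counts scaled from TPM for summed genes, and leaving out each library. Pairs of libraries of a group differed by far more than sampling noise (chi-square per degree of freedom 15.6 to 41.3 over transcripts with at least 10 reads in the pair), so none was counted as a duplicate.

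The tests were tried on simulated libraries of the same 29566 transcripts, spread and depth, with 200 changed transcripts. Each transcript had the same spread in both groups, and far fewer transcripts changed than were called in the data. With transcripts of at least 1 CPM, edgeR recovered 0% of 2-fold, 4.5% of 4-fold and 16.7% of 8-fold changes with 0 false calls. A setting with transcripts of at least 10 CPM was added after that result: edgeR recovered 20.9% of 4-fold, 49.3% of 8-fold and 48.5% of 16-fold changes with 3 false calls. DESeq2 recovered more (6% of 2-fold and 40.3% of 4-fold in the first setting, 65.7% of 4-fold in the other) but made 215 and 277 false calls. For limma the simulated counts were scaled to CPM and not to TPM, so its figures are for log2(CPM + 1). In the first setting limma recovered 0% of 2-fold, 9% of 4-fold and 25.8% of 8-fold changes with 1 false call. In the other it recovered 31.3% of 4-fold, 55.2% of 8-fold and 59.1% of 16-fold changes with 7 false calls. The direction was right for 100% of recovered changes. A test of differential transcript usage in edgeR was also tried on simulated data and set aside, since it made more false calls than its threshold allows. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for shares, closing tests and figures.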

Results

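Translating RNA was profiled in Purkinje cells differentiated from RUES2, an established line of human embryonic stem cells. The assay, translating ribosome affinity purification (TRAP), recovers polysome-bound RNA through a GFP-tagged ribosomal protein, here from cells labelled as Pcp2-TRAP. Pcp2 is a gene characteristic of Purkinje cells. Libraries were made at Day 24 of differentiation (n = 3) and at a later point, Day +95, counted from when the human cells were placed with mouse granule cells and glia (n = 3). The estimated reads per library ranged from 8412364 to 12625477 at Day 24 and from 8280633 to 12313578 at Day +95. The comparison asked how the translated RNA of the cells differed between the time points. Because co-culture with mouse cells and time changed together, no value below separates one from the other. No input or unbound RNA was analysed here, so enrichment by the purification was not measured. The labels do not say that the replicates were separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

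The deposited files list transcripts and do not pair them with genes. A small sample of the matching transcript annotation named 146 of the 69548 transcripts, belonging to 43 genes. These genes were not chosen for Purkinje cell biology or for their values. The 33 gene lists and 6 genes fixed before the data were examined, which included markers of Purkinje cells and of other cell types, were therefore not tested. Of the 43 genes, 27 had enough reads for a test on summed transcripts, 8 of them rose at Day +95, 5 fell and 14 did not pass the threshold (edgeR quasi-likelihood test, adjusted p under 0.05). Adjusted over the 27 genes alone, 13 also passed. That 48.1% of these genes passed stands beside 30.5% of all transcripts tested singly, and these shares were not compared by a test.

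Among the genes that rose, PRPF39, a pre-mRNA splicing factor, went from 34.4 ± 2.5 to 188 ± 41 CPM (the read count normalised to the library total and the TMM factor, mean ± SD, n = 3 each). Its log2 fold change was 2.45 (SE 0.20, edgeR adjusted p = 7.01e-04). This is the rise of its summed transcripts, and the one with the longest coding sequence fell to 0 reads at Day +95. R3HDM1, an R3H domain gene, rose from 25.1 ± 5.6 to 159 ± 31 CPM, a log2 fold change of 2.66 (SE 0.24, edgeR adjusted p = 9.31e-04). PHF8, a histone demethylase, rose by 2.32 on the log2 scale (SE 0.51, edgeR adjusted p = 0.0163). RIF1, a regulator of replication timing and of DNA break repair, rose by 1.34 (SE 0.36, edgeR adjusted p = 0.0349). Of its 603 reads at Day 24 and 1373 at Day +95, 28 and 761 were of uc010zby.1, a transcript without a coding sequence. With counts scaled from TPM the log2 fold change of RIF1 was 2.62, and its call was lost in 8 of 15 alternatives, among them library totals (edgeR adjusted p = 0.0521) and no low-count filter (0.0567). SRPK1, a kinase of SR splicing factors, rose by 0.97 (SE 0.19) and CLCN4, a chloride/proton exchanger, by 0.96 (SE 0.18). The SRPK1 transcript with the longest coding sequence, uc003olj.3, did not rise, with 1146 reads at Day 24 and 690 at Day +95. Its log2 fold change was -0.55 (edgeR adjusted p = 0.18). Another SRPK1 transcript, uc011dtg.2, had 141 and 1557 reads (log2 fold change 3.49, edgeR adjusted p = 0.106). With limma on log2(TPM + 1), SRPK1 (0.53) and CLCN4 (0.56) did not pass (adjusted p = 0.112 each, over their alternatives 8.98e-04 to 0.112 and 1.65e-04 to 0.112). The median log2 fold change of all tested transcripts was also lower with limma, which used no TMM factor, at -0.40 against -0.19 with edgeR. LHFPL6, a tetraspan membrane protein, was the most abundant of the 27 genes and rose from 283 ± 19 to 490 ± 75 CPM, by 0.79 (SE 0.14, edgeR adjusted p = 0.00886, and 0.0709 with limma). MLC1, an astrocyte membrane protein in the brain, had 0 reads in the Day 24 libraries and 127 reads in the Day +95 libraries, which ranged from 12 to 82 reads each. With 3 counts over the Day 24 libraries as the floor, MLC1 was at least 43.1-fold higher (edgeR adjusted p = 0.0186), and at least 25.2-fold without Day +95 replicate 3.

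Among the genes that fell, SKA3, part of the complex that couples kinetochores to spindle microtubules in mitosis, went from 507 reads at Day 24 to 7 reads at Day +95. Its CPM fell from 15.9 ± 2.6 to 0.24 ± 0.32, a log2 fold change of -5.97 (SE 1.28, edgeR adjusted p = 0.0154). IQCC, an IQ motif gene, went from 174 to 4 reads, a log2 fold change of -5.31 (SE 1.16, edgeR adjusted p = 0.0165). TFAP2A-AS1, a non-coding RNA antisense to TFAP2A, went from 87 to 7 reads (log2 fold change -3.52, SE 0.86). Strand is not stated for the counting, so reads of TFAP2A-AS1 and of an overlapping gene cannot be told apart here. CERCAM, a cell adhesion gene, fell by 1.38 (SE 0.35) and ARMCX3, an outer mitochondrial membrane protein, by 0.45 (SE 0.13, edgeR adjusted p = 0.0411). With no low-count filter, TFAP2A-AS1 and ARMCX3 lost the call (edgeR adjusted p = 0.134 and 0.1, over their alternatives 0.00185 to 0.16 and 6.68e-04 to 0.148). Over all 27 tested genes, whether or not they passed, the groups did not overlap in 18 (66.7%), among them 5 that did not pass. By chance 10% would be expected with 3 against 3, and over all tested transcripts the groups did not overlap for 56.5%.

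**Figure D1:**
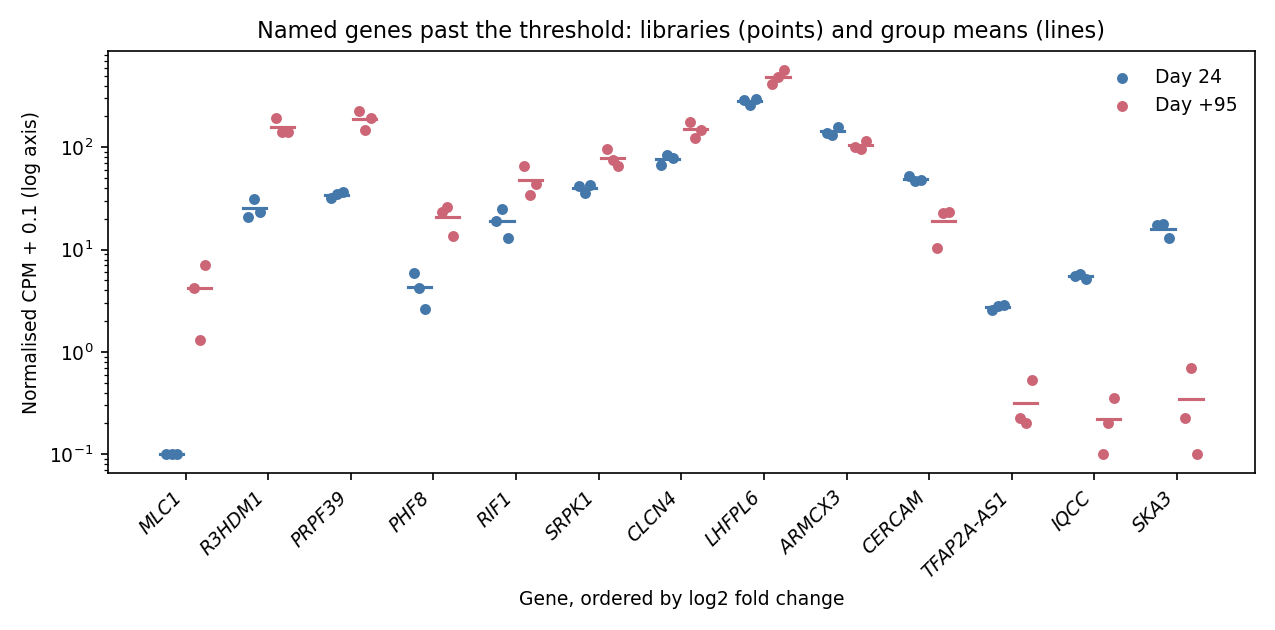
Normalised CPM plus 0.1 on a log axis for the 13 named genes past the threshold. Points are the 3 libraries of each group and lines are group means; the groups do not overlap for any of these genes, and MLC1 had 0 reads at Day 24.

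The 14 genes that did not pass include some with few reads and wide spread. ZDHHC23, a palmitoyltransferase, had 8 reads at Day 24 and 105 at Day +95 (log2 fold change 3.88, SE 1.44, edgeR adjusted p = 0.0936). Day 24 replicate 3 held 7 of the 8 reads, and without it the log2 fold change was 5.85 (edgeR adjusted p = 0.0755). AMPD3, an AMP deaminase, had 61 and 315 reads (edgeR adjusted p = 0.107), and C4orf46 had 1380 and 193 reads, of which the Day +95 libraries held 0, 152 and 41 (log2 fold change -2.78, edgeR adjusted p = 0.191, and -4.54 without Day +95 replicate 2). The transcription factor genes PITX1 (log2 fold change 0.41, SE 0.69) and ETV6 (-0.28, SE 0.44) were also below the threshold. For ETV6 the log2 fold change was -1.22 with counts scaled from TPM, and -1.15 with limma on log2(TPM + 1), which called it (adjusted p = 0.0383, over its alternatives 0.0383 to 0.935). Its main transcript, the 5978-nt uc001qzz.3, changed by -0.20 (SE 0.44, edgeR adjusted p = 0.778). The 579-nt uc001raa.1, which weighs more in TPM than in counts, had 24 reads at Day 24 and 0 at Day +95. ZDHHC23 and AMPD3 passed with DESeq2 and with limma, and C4orf46 and ZNF107 with limma. Also below the threshold were ZNF107, ATF7IP2, PFKFB2, SARS2, TBC1D12, DXO, FAM199X, MSTO2P and A1BG. In simulated libraries of this spread, the test recovered 0% of 2-fold changes among transcripts of at least 1 CPM and 20.9% of 4-fold changes among those of at least 10 CPM. Those libraries had 200 changed of 29566 transcripts, against 9011 called in the data, and the same spread in both groups. Recovery in the data may therefore differ. Either way, a gene below the threshold is not shown to be unchanged. MSTO2P is a pseudogene that can share reads with related copies, and DXO and SARS2 have neighbours that can overlap them, which the counting may not separate.

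Of the 27 genes, 4 passed without Day 24 replicate 1, 4 without Day 24 replicate 2 and 5 without Day 24 replicate 3. Without Day +95 replicate 1, 2 or 3, the numbers were 9, 10 and 11. For 7 genes, SKA3, MLC1, RIF1, IQCC, TFAP2A-AS1, CERCAM and ARMCX3, leaving out any single Day 24 library ended the call. The edgeR adjusted p was then 0.0528 to 0.0584 for SKA3, 0.0536 to 0.0554 for MLC1 and 0.0599 to 0.108 for RIF1. PHF8 lost its call without Day 24 replicate 2 or 3 (0.066 and 0.0539), SRPK1 without Day 24 replicate 1 or 2 (0.0525 and 0.0602) and CLCN4 without Day 24 replicate 1 (0.0509). Among Day +95 libraries, replicate 1 ended the call of MLC1 (0.0609), RIF1, TFAP2A-AS1 and ARMCX3, replicate 2 that of IQCC, TFAP2A-AS1 and ARMCX3, and replicate 3 that of MLC1 (0.055) and RIF1. Without Day +95 replicate 2, which held 6 of the 7 SKA3 reads of that group, the log2 fold change of SKA3 was -7.89. Without Day +95 replicate 3 it was -5.34 for SKA3, -6.34 for IQCC and -4.40 for TFAP2A-AS1. PRPF39 and R3HDM1 passed under each of the 15 alternatives tried.

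Within genes, the assignment of reads to transcripts also differed between the time points. Of 51 named transcripts tested, 10 rose and 7 fell (edgeR, adjusted over all transcripts tested). Of these 17 calls, 12, 9 and 9 held without Day 24 replicates 1, 2 and 3, and 14, 15 and 14 without Day +95 replicates 1, 2 and 3. Of the 7 that fell, 3, 2 and 2 held without Day 24 replicates 1, 2 and 3, and 4 (uc001bum.2 of IQCC, uc010mya.1 of CERCAM, uc002czu.3 of ATF7IP2 and uc002oka.2 of SARS2) lost the call when any single Day 24 library was left out. With no low-count filter, 4 of the 7 held. With the replicate number as a block, 6 of the 17 calls held, all of them rises, and 0 of the 7 falls. In 13 genes with at least 50 reads in every library, 22 of 50 transcripts (44%) had shares of their gene's reads that did not overlap between the groups, against 10% expected by chance. Shares within a gene depend on each other, so these transcripts are not independent, and the 22 lay in 11 of the 13 genes. A two-sided exact permutation test of 1 share cannot give p below 0.1 here. These shares rest on the authors' estimates from single reads, with no bootstrap estimates used here.

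PRPF39 (chromosome 14, 45553302 to 45584804, + strand, hg19) changed in which transcripts it was assigned to. Transcript uc001wvz.4, which skips the 335-nt exon at 45565627 to 45565961, made up 39.5% ± 6.5 of its reads at Day 24 (SD, n = 3) and 0% at Day +95, with 451 and 0 reads. As the reads were assigned, it was at least 148-fold lower (edgeR adjusted p = 0.00443). Its annotated coding sequence of 2010 nt is the longest, against 1647 nt in uc001wvy.4, 1380 nt in uc010and.3 and 819 nt in uc001wwa.1. The rise of the summed gene was therefore not a rise of that form. Transcript uc010and.3 runs unspliced through that exon and the introns on both sides, in a single exon from 45565306 to 45566208. Its share was 2.7% ± 3.5 at Day 24 and 57.8% ± 0.40 at Day +95 (log2 fold change 6.76, SE 1.02, edgeR adjusted p = 0.00551). Its Day 24 libraries held 0, 25.7 and 6.7 reads, and without Day 24 replicate 2 the log2 fold change was 8.38 (edgeR adjusted p = 0.00834). The short transcript uc001wwa.1, which keeps a pair of introns nearer the 3' end, had shares of 3.5% ± 2.7 and 10.0% ± 1.2. Together the transcripts that keep an intron held 6.2% ± 3.9 and 67.8% ± 1.4 (exact permutation p = 0.1, the smallest possible). The transcript uc001wvy.4, with the exon spliced in, rose in CPM by 1.70 on the log2 scale (SE 0.24) while its share went from 54.3% ± 2.6 to 32.2% ± 1.4.

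**Figure D2:**
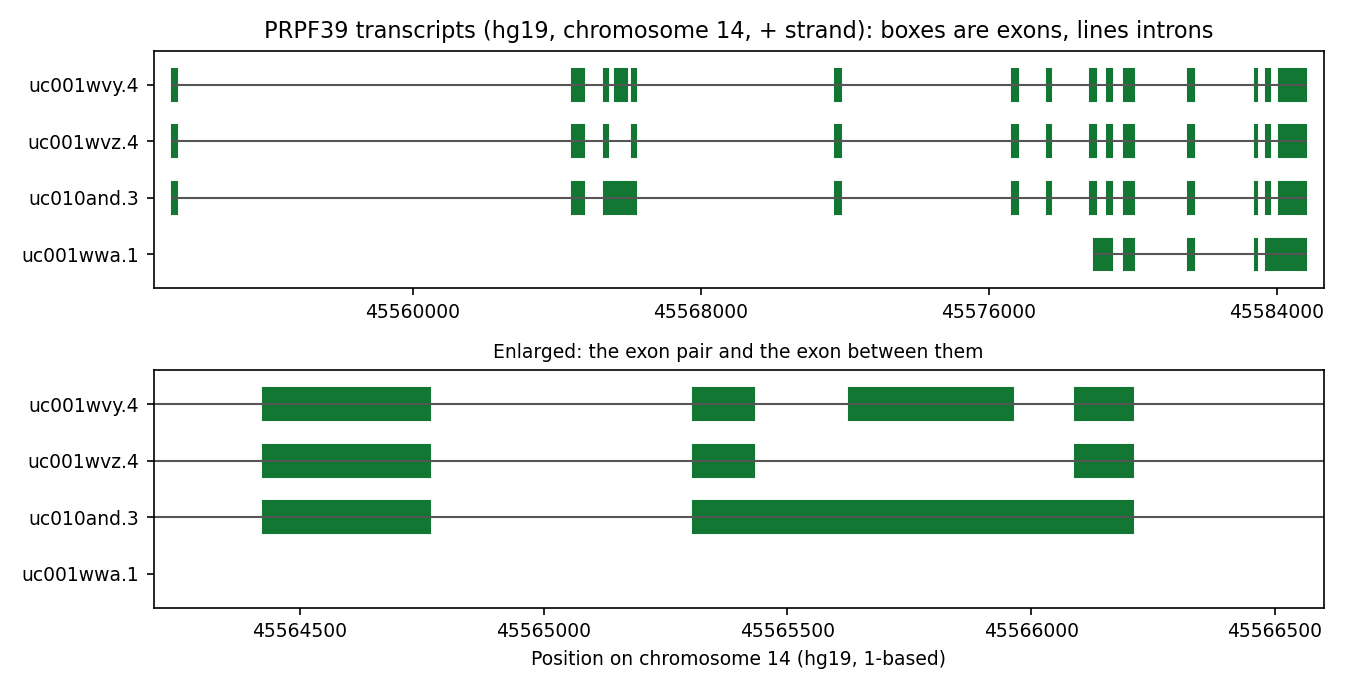
Exons (boxes) and introns (lines) of the 4 PRPF39 transcripts on chromosome 14 of hg19, 1-based positions, with the region around the 335-nt exon enlarged. Transcript uc010and.3 has a single exon from 45565306 to 45566208 where uc001wvy.4 has 3.

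CLCN4 (chromosome X, 10124985 to 10205699) was assigned only to its 13-exon transcript at Day 24. The 11-exon transcript uc011mid.3, which lacks exons 3 and 4 of the longer one (155 and 100 nt), had 0 reads at Day 24 and 1884 at Day +95. As the reads were assigned, it was at least 639-fold higher (edgeR adjusted p = 7.06e-04) and held 44.2% ± 16.2 of the reads of the gene. That bound does not cover error in assigning reads between the transcripts of the gene. The longer transcript had 2521 and 2487 reads (log2 fold change 0.16, SE 0.35, edgeR adjusted p = 0.772). For R3HDM1, transcript uc010fni.3, which begins downstream of the first exon of uc002tuo.3, went from 32.4% ± 11.5 to 0% of reads, and its call was lost without Day 24 replicate 2 or 3 (edgeR adjusted p = 0.0528 and 0.0514). For RIF1, the 15-exon transcript uc010zby.1 without a coding sequence rose from 5.6% ± 4.9 to 56.2% ± 6.0 (log2 fold change 4.80, SE 0.92, edgeR adjusted p = 0.0114, and 0.0523 without Day 24 replicate 3). Without Day 24 replicate 1 its log2 fold change was 5.95. The RIF1 transcripts with a coding sequence of 7341 or 7419 nt did not rise from Day 24 to Day +95. The reads were 165 and 137 for uc002txm.3, 102 and 0 for uc002txn.3, 85 and 11 for uc002txo.3, and 40 and 0 for uc002txl.3. They were uneven between the Day 24 libraries, and only uc002txm.3 was tested (log2 fold change -0.0056, SE 1.61, edgeR adjusted p = 0.998). For SARS2, whose total did not pass, uc002oka.2 fell from 63.7% ± 6.5 to 0.59% ± 1.0 and uc002ojz.2 rose from 0% to 39.5% ± 21.3. The edgeR adjusted p of uc002oka.2 was 0.021, and 0.0702, 0.0609 and 0.0747 without Day 24 replicates 1, 2 and 3.

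**Figure D3:**
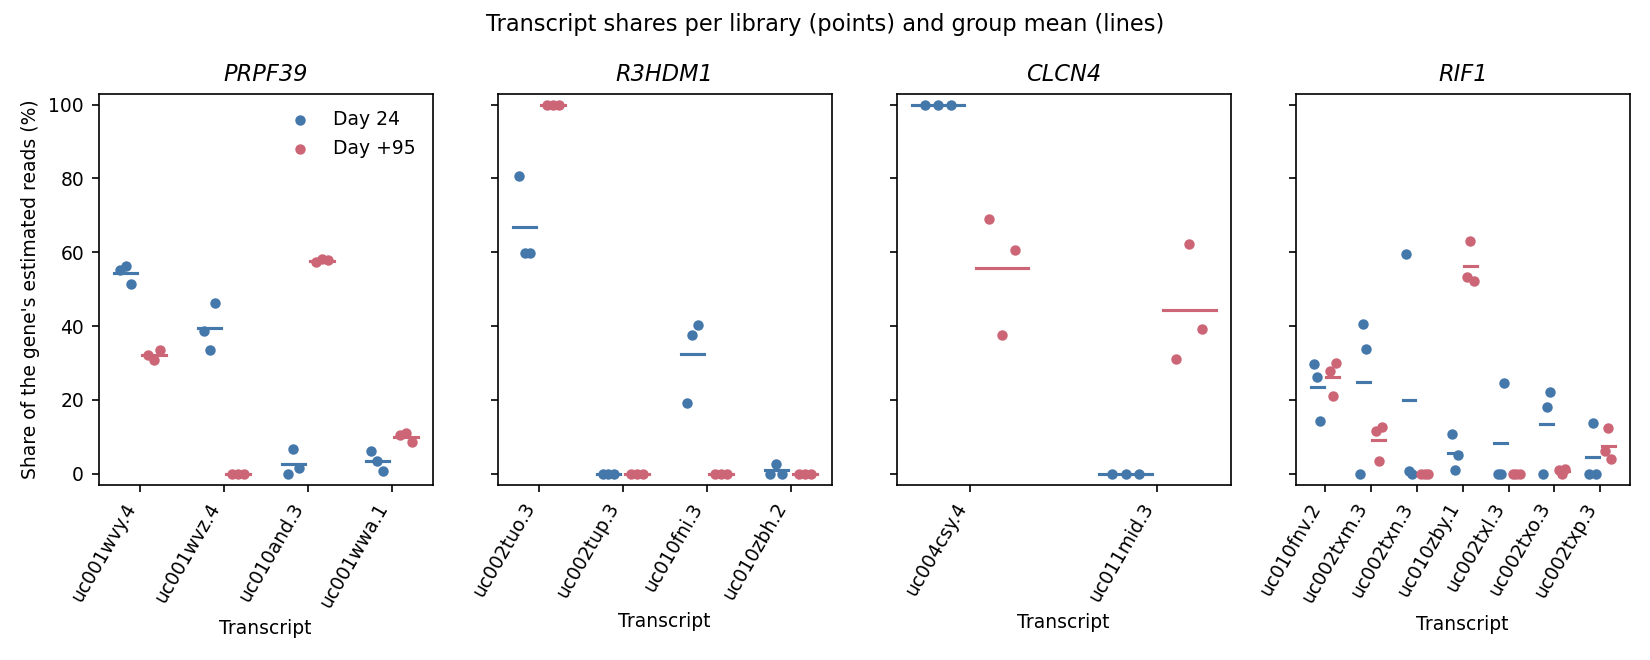
Share of a gene's estimated reads (percent) for each transcript of PRPF39, R3HDM1, CLCN4 and RIF1. Points are the 3 libraries per group and lines are group means; uc010and.3 of PRPF39 lies near 57.8% in the Day +95 libraries against a mean of 2.7% at Day 24.

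Over all transcripts, 29566 were tested and 9011 changed at an adjusted p under 0.05 (edgeR), 4616 higher and 4395 lower at Day +95. At least 2-fold changes numbered 8176, of which 4187 were higher and 3989 lower. At an unadjusted p under 0.05 there were 11889. The groups did not overlap for 56.5% of tested transcripts, against 10% by chance. The count of changed transcripts was 5443 without Day 24 replicate 1, 5327 without Day 24 replicate 2 and 5681 without Day 24 replicate 3. Of these, 2189, 2082 and 2192 were lower, so that 59.8%, 60.9% and 61.4% of calls were higher, against 51.2% with all libraries. With limma on log2(TPM + 1), 5058 were higher and 9512 lower. By the rule for the largest changes, uc002knm.3 and uc002knl.3 had 47377 and 26931 reads at Day 24 and 0 at Day +95, at least 15517-fold and 8820-fold lower. Transcripts uc011cen.1 and uc031shy.1 had 0 reads at Day 24 and 29676 and 22750 at Day +95, at least 10068-fold and 7718-fold higher. For uc031shy.1 the Day +95 libraries were at 1589, 159 and 727 CPM, and without Day +95 replicate 1 the bound was 4669-fold. The files do not pair these IDs with genes, and the bounds take the assignment of reads to transcripts as given.

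Fewer transcripts were detected at the later time point. At least 1 read was assigned to 36521 ± 1016 transcripts at Day 24 and 31251 ± 1609 at Day +95 (SD, n = 3 each, two-sided exact permutation p = 0.1, the smallest that 3 against 3 allows). At the depth of the smallest library the expected numbers were 36134 ± 768 and 30960 ± 1354. Across tested transcripts, which are not independent replicates, Pearson's r of log2 CPM was 0.83 to 0.84 within Day 24, 0.76 to 0.77 within Day +95 and 0.37 to 0.45 between the groups.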

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

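Alternatives were planned before the data were examined. List tests were not run, for lack of gene names. Without names, mitochondrial transcripts were not removed beside the 20 most abundant. Counts scaled from TPM equal rescaled counts for single transcripts and were run for summed genes only. The numbers of transcripts changed, higher, lower and changed at least 2-fold stayed within 1.5 times of 9011, 4616, 4395 and 8176 with DESeq2's size factors in edgeR, library totals, no filter and without the 20 most abundant transcripts. No alternative called a transcript of the 9011 in the opposite direction. Library totals moved the median log2 fold change of all transcripts from -0.19 to -0.30. With a mean of at least 10 CPM, fewer transcripts were tested, 2862 were lower and 5209 changed at least 2-fold. DESeq2 called 6856 lower, with many false calls on simulated data. With limma on log2(TPM + 1), 14570 changed and 9512 were lower, so that 34.7% of calls were higher against 51.2%. The median log2 fold change was -0.40, and no TMM factor was applied to TPM. For LHFPL6, CLCN4 and SRPK1 the log2 fold changes were 0.40, 0.56 and 0.53. With counts scaled from TPM and a TMM factor they were 0.79, 0.98 and 0.97, so the shift was not limited to genes with few reads. SKA3, with 7 reads at Day +95, was at -2.88 with limma and -5.95 with those counts. The cause was not tested. Leaving out 1 library gave 5327 to 9342 changed, 3245 to 4080 higher, 2082 to 5262 lower and 5100 to 8755 changed at least 2-fold. The lowest came from leaving out a Day 24 library.

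The replicate numbers are shared between groups. Same-numbered libraries did not deviate together in expression (correlations of deviations -0.0014, -0.015 and -0.0026). Their estimated reads were close, at 8412364 and 8280633 for replicate 1, 10696397 and 10586025 for replicate 2, and 12625477 and 12313578 for replicate 3. Whether they shared a handling step is therefore not settled. With the replicate block, which uses up residual degrees of freedom, 3075 changed, 1845 were higher, 1230 lower and 2887 changed at least 2-fold, and 3 named genes passed. Of the 27 tested named genes, 13 passed with edgeR and all libraries, 4 to 11 when 1 library was left out and 9 to 15 under the alternatives other than the block. LHFPL6 passed in all settings but limma (adjusted p 0.0709; over its 15 alternatives 4.06e-08 to 0.0709). Genes below the threshold that changed sign were MSTO2P (-0.034 to 1.01 when 1 library was left out), DXO (-0.16 to 0.010), FAM199X (-0.34 to 0.27) and A1BG (-0.32 to 0.22). For A1BG the log2 fold change was also -0.015 with DESeq2, -0.011 with its size factors, -0.087 with library totals, -0.38 with limma and -0.035 with the block. The cause was not tested. None of the 10 splits of the libraries other than the real one called a transcript or a named gene (highest other count 0, against 9011, 4616, 4395, 8176 and 13 in the real split, which was the 1 split as large), but 10 splits cannot give a share under 0.05. Each other split puts libraries of both groups on each side, so the difference between the groups enters the spread. A count of 0 is then likely and does not measure the rate of false calls.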

Other observations

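The tests of neighbouring transcripts, intron-keeping transcripts and mouse reads, and the count over splits of the libraries, were chosen after the results were seen. Of the 43 named genes, 16 had too few reads for a test. TLR2, an innate immune receptor, the olfactory receptor genes OR12D2 and OR2K2, UROC1, an enzyme of histidine breakdown, and GAB3, LRRC52 and EHHADH-AS1 had 0 reads in all 6 libraries, which allows up to 0.0945 CPM over Day 24 and 0.0962 CPM over Day +95. S100A9, a calcium-binding protein of myeloid cells, had 0 reads at Day 24 and 14 at Day +95, 0 of them in Day +95 replicate 3. ZP3, a zona pellucida gene, had 28 and 1 reads, and BCAS1, an oligodendrocyte gene, 3 and 0. SERPINB4, which has a close paralog, had 15 and 59 reads.

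By transcript length, 278 of 1085 tested transcripts longer than 8000 nt rose and 99 fell (73.7% of changed transcripts higher, median log2 fold change 0.86). In the 5 classes of over 250 and up to 8000 nt, 46.6% to 60.4% of changed transcripts were higher and the medians were -0.35 to -0.04. Of 36 transcripts of up to 250 nt, 17 rose and 3 fell (median 2.84). Differences between the classes were not tested. The share of reads on transcripts longer than 8000 nt overlapped between the groups (2.23% ± 0.34 at Day 24 and 2.59% ± 0.30 at Day +95, SD, n = 3 each, two-sided exact permutation p = 0.3). Transcripts shorter than 250 nt held 0.0129% ± 0.0017 of reads at Day 24 and 0.107% ± 0.032 at Day +95 (SD, n = 3 each, two-sided exact permutation p = 0.1, the smallest possible), and 2 transcripts held 86.3% of those at Day +95.

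Some abundant transcripts vanished. Of 3312 transcripts at 50 CPM or more in every Day 24 library, 35 had under 1 read in every Day +95 library, and 38 of 2943 showed the converse. Reads may have been assigned to a neighbouring transcript instead. Random positions were drawn from the other transcripts past the same minimum, which kept reads in the other group. Vanished transcripts in nearby rows can share a gaining row, so they are not independent and the p-values may be too small. For 20 of the 35 the 5 rows on either side together gained at least 50% of the lost amount, against 29.3% at random positions (1000 draws, permutation p = 0.000999, the smallest possible). For the converse it was 11 of the 38 against 28.1% (permutation p = 0.528). These are 2 of 100 overlapping tests, over 5 abundance minimums, 5 numbers of rows (1, 2, 5, 10 and 20) and the summed or the highest single gain (for which 19 of the 35 and 8 of the 38 qualified): for Day 24, 32 of 50 had p under 0.05 and 28 kept it after Benjamini-Hochberg adjustment over the 100 (0.025 for the 20 of 35), and for Day +95, 0 of 50 with or without adjustment. The result for Day 24 depended on the abundance minimum. Past the adjusted threshold were 1 of 10 tests at 10 CPM, 3 at 20, 9 at 50, 8 at 100 and 7 at 200. In all 32 named genes with 2 or more transcripts, the transcripts lie in consecutive rows. A real switch within a gene would therefore raise neighbouring rows as well. At no minimum can the test tell reassignment and real switches of transcript or gene apart.

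At Day +95 the PRPF39 transcripts that keep introns held 67.8% of its reads. A general rise of intron-containing RNA in the Day +95 libraries would raise such shares in other genes, but among the 5 others with intron-keeping transcripts the highest change was 0.269 percentage points, and DXO was lower in every Day +95 library. For these 5 genes the values argue against a rise of the size seen in PRPF39. Their intron-keeping transcripts had few reads at Day 24 and Day +95 in SRPK1 (9 and 18), DXO (22 and 7) and SARS2 (13 and 10). Introns kept in no annotated transcript were not counted, so a general rise is not excluded. Mouse reads counted on human transcripts stay open for the 5509 PRPF39 reads at Day +95, since co-culture and time changed together. The same stays open for every other rise or change of transcript at Day +95. Examples are R3HDM1 (4601 reads) and uc011mid.3 of CLCN4 (1884 reads). The purification through the GFP tag is, however, meant to remove RNA of cells without the tag. Also open is a change of PRPF39 processing in the cells, a hypothesis that was not tested.

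MLC1 was read only at Day +95, by 127 reads. Mouse cells of the co-culture may have given these reads, or the human cells may have expressed the gene at the later time. The purification through the GFP tag is a step meant to remove RNA of cells without the tag, and how far it did so was not measured here. The design confounds these sources and no mouse sequence was used here, so they cannot be told apart.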
